A study of Homo sapiens with 60 samples.

How the data were processed

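Gene expression was measured on Affymetrix arrays in RNA from whole skin punch biopsies, taken from healthy persons and from non-lesional skin of persons with psoriasis. Biopsies were taken at baseline or 24 hours after an intradermal injection of placebo or of interferon-gamma (IFNγ), a cytokine made mainly by T cells and natural killer cells. Lesional skin was not used here. The deposited values were log2 signals of 22277 probe sets in 60 arrays, made by the authors with GCRMA per the submitters' processing notes. The version of that tool was not given in the sources used here. Values ran from 2.08 to 15.91, and 26.9% of them lay at the lowest value (within 1e-06). Some probe sets had a lowest value above 2.08, so the floor below refers to values near or under 3 (log2). A change in a gene that sits at the floor in one group may be understated. Array medians ran from 5.08 to 5.40, and no further normalization was applied. Scanner files were not used here. For arrays, their number limits the precision.

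Groups and persons were read from the titles and characteristics. Of the 60 arrays, 56 fell into 6 groups: healthy skin at baseline (10 arrays), after placebo (8) and after IFNγ (8), and psoriatic non-lesional skin at baseline, after placebo and after IFNγ (10 each). They came from 20 persons, 10 healthy and 10 with psoriasis; a replicate number names a person within the healthy or the psoriatic set, so healthy replicate 5 and psoriasis replicate 5 are different persons. For 4 arrays of 2 healthy persons, the title gives one injection and the characteristic the other. These arrays were put in no group, and their values are given separately. The pairing of arrays by person was taken from the titles and checked on the values: after removing group means, 54 pairs of arrays of the same person had a median correlation of 0.417 across genes, with 52 pairs over 0.1, against -0.052 in 470 pairs of different persons. No array pair was a duplicate.

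Of the probe sets, 19070 carried 1 gene symbol in the deposited probe table, 1043 several and 2164 none. Gene identifiers of 19058 of the 19070 matched the reference table. Probe sets with several or no symbols (1548 after the filter below) are given only as counts, and no gene was named for them. Because the donors are human, 31 probe sets of genes that can reveal sex were left out before any test. Probe sets were kept when above 3 (log2) in at least 8 arrays, the size of the smallest group. Each gene was read from its probe set with the highest mean, which left 8446 genes.

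One linear model with the 6 groups was fitted to the 56 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), with person as a random block through duplicateCorrelation (estimated correlation 0.449). The 8 comparisons were IFNγ against placebo in healthy and in psoriatic skin, the difference between these responses, placebo against baseline in each, and psoriatic against healthy skin at baseline, after placebo and after IFNγ. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, within each comparison, and at least 2-fold (1 on the log2 scale). All tests were two-sided. Placebo arrays enter the IFNγ comparison and the placebo comparison of the same disease state with opposite sign, so these share controls. Values are given as log2 fold change with SE, and levels as mean ± SD. On simulated data with 8446 genes and the same design, 76%, 100%, 98% and 96% of 50 genes each, changed by 0.6, 1.2, 2 and 3 log2, were recovered at the adjusted p for IFNγ against placebo in healthy skin, with 12 false calls. For the difference between responses these shares were 52%, 84%, 98% and 100%, with 13 false calls. For psoriatic against healthy skin at baseline they were 52%, 96%, 96% and 98%, with 7 false calls. The changed genes were drawn at random from better expressed genes only, with noise that was normal and independent between genes. These shares therefore do not describe weakly expressed genes, nor the genes that respond to IFNγ as a set.

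Gene lists, 36 in all, were fixed before the data were examined, as were the groups, the design, the thresholds and the rule for named genes. In the lists, "rose" and "fell" refer to members past adjusted p 0.05 at any fold. Each list was tested against all other genes with cameraPR at a preset inter-gene correlation of 0.01, and again with camera at an estimated correlation on per-person differences, or on the arrays for comparisons between persons. In every one of the 8 comparisons, 0 lists passed with an estimated correlation, so each list call by these tests below rests on the preset value. Where placebo arrays enter, the estimate included those of healthy replicate 5 and psoriasis replicate 5, which lay far from their groups. It was not repeated without them. A further test was chosen after seeing the data: the mean change of a list was computed per person and tested by exact sign-flip permutation, or by permuting persons between the disease groups (100000 resamples for the baseline comparison). This last test asks whether a list moved from person to person and does not compare it with other genes. Its smallest possible p was 0.00781 with 8 persons.

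Named genes followed a fixed rule. Per comparison they were up to 15 with the largest rise and 15 with the largest fall among genes past the threshold that moved the same way in every person, up to 4 members of each list with the smallest adjusted p, and CXCL10, CXCL9, IRF1, IDO1 and HLA-DRA as known IFNγ targets. Where fewer than 3 genes passed, the 5 with the smallest p are given. One further target of that rule is not reported here. Probe sets whose identifier ends in x_at or s_at can bind related transcripts, so single members of families such as HLA genes are less certain.

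RNA quality was read from the 3' minus 5' log2 difference of the GAPDH and ACTB control probe sets. Alternatives covered the person block, the arrays in the fit, the filter, normalization, the choice of probe set and the variance model. They also covered array weights, thresholds, the control of IFNγ and leaving out each person. Gene counts with baseline as that control are not given here. Chosen after seeing the data were 3 more: leaving out the placebo arrays of healthy replicate 5 and psoriasis replicate 5, adding the ACTB difference as a covariate, and leaving out the 7 arrays with a GAPDH or ACTB difference of 1.5 or more. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No genome build is stated, and no coordinates are given.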

Results

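Group means of known IFNγ targets were highest after IFNγ in both disease states, with 2 placebo arrays near the IFNγ level. CXCL10, which encodes a chemokine that draws activated T cells, had a log2 level of 5.7 ± 2.64 (SD, n = 10) in healthy skin at baseline, 9.48 ± 2.44 (n = 8) after placebo and 15.17 ± 0.10 (n = 8) after IFNγ. In psoriatic non-lesional skin (n = 10 per group) its levels were 6.99 ± 2.53, 8.90 ± 2.61 and 15.06 ± 0.13. IDO1, which encodes an enzyme that breaks down tryptophan, lay near the floor at baseline (2.60 ± 0.09 in healthy and 2.72 ± 0.29 in psoriatic skin) and reached 13.41 ± 0.30 and 13.48 ± 0.32 after IFNγ. The transcription factor gene IRF1 went from 6.03 ± 1.2 at baseline to 9.52 ± 1.63 after placebo and 13.21 ± 0.15 after IFNγ in healthy skin, and from 6.30 ± 0.91 to 8.98 ± 1.39 and 13.16 ± 0.21 in psoriatic skin. CXCL9 reached 15.14 ± 0.07 and 15.13 ± 0.06 after IFNγ. CXCL9 and CXCL10 were thus near the top of the scale in every IFNγ array, so differences between IFNγ arrays could not be read for these genes and their fitted rises may be understated. The exceptions among placebo arrays were healthy replicate 5, with IRF1 at 12.98 after placebo and 12.97 after IFNγ, and psoriasis replicate 5, with HLA-DRA at 14.32 and 13.97.

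**Figure D1:**
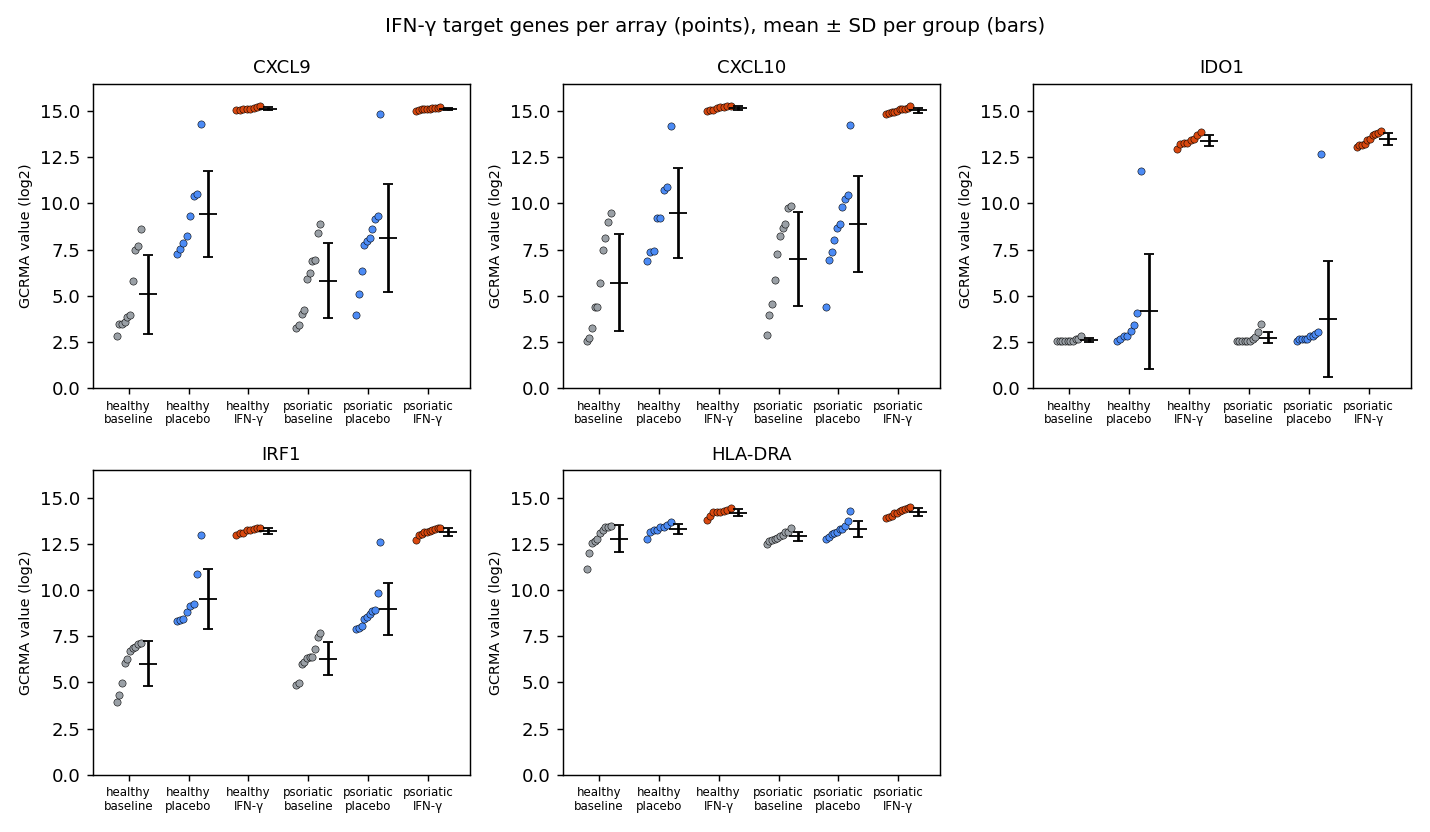
Log2 GCRMA signal of CXCL10, CXCL9, IRF1, IDO1 and HLA-DRA in each array of the 6 groups, with the group mean and SD; points within a group are sorted by level. The placebo arrays of healthy replicate 5 and psoriasis replicate 5 have IDO1 levels of 11.77 and 12.69, where the next placebo arrays have 4.05 and 3.06.

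After IFNγ, interferon-inducible genes rose against placebo in healthy skin. Among 8446 genes, 562 rose and 430 fell at adjusted p under 0.05 and at least 2-fold (992 in all), and 4341 passed at any fold (2009 higher, 2332 lower). The largest fitted rise was in IDO1, by 9.26 (SE 0.77, adjusted p = 1.22e-14, higher in 8 of 8 persons), or 10.37 without the 2 outlying placebo arrays. It may be understated, as most placebo arrays lay near the lowest value of its probe set. OASL, an antiviral gene of the oligoadenylate synthetase family, rose by 7.95 (SE 0.41, adjusted p = 7.58e-22), and RSAD2, an antiviral enzyme gene, by 7.48 (SE 0.57). Both lay near the floor at baseline too, as did IFIT2 and RTP4, so the order of the largest rises is not exact. Further rises in 8 of 8 persons were in PLA1A (6.92), CXCL11 (6.74, SE 0.72), CCL8 (6.72), PLAC8 (6.65), OAS2 (6.29), RTP4 (6.23), IFIT2 (6.21), RGS1 (5.94), ISG20 (5.90) and IFI6 (5.56). CXCL9 rose by 5.72 (SE 0.85, adjusted p = 1.52e-07) and CXCL10 by 5.68 (SE 0.89, adjusted p = 4.71e-07), both limited by the top of the scale. SOCS1, a feedback inhibitor of cytokine signalling, rose by 5.41 (SE 0.46). IRF1 rose by 3.68 (SE 0.47, adjusted p = 3.09e-09) and was higher in 7 of 8 persons. HLA-DRA, an antigen-presenting class II gene with a high level at baseline, rose by 0.90 (SE 0.17, adjusted p = 1.38e-05), which is under 2-fold.

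In psoriatic non-lesional skin, 641 genes rose and 629 fell after IFNγ against placebo (1270 in all, 2119 higher and 3076 lower, 5195 in all, at any fold). IDO1 rose by 9.74 (SE 0.69, adjusted p = 1.83e-17), OASL by 7.96 (SE 0.37, adjusted p = 3.87e-24) and RSAD2 by 7.68 (SE 0.51), each in 10 of 10 persons. These genes, FCGR1BP, IFIT2 and RTP4 lay near the floor at baseline, so the order of the largest rises is not exact here either. FCGR1BP, related to the high-affinity immunoglobulin receptor of myeloid cells and read by a probe set that can bind related transcripts, rose by 7.35 (SE 0.60). CXCL11 rose by 7.34 (SE 0.64, adjusted p = 2.62e-14), CXCL9 by 7.01 (SE 0.76, adjusted p = 2.34e-11), CCL8 by 6.99, PLAC8 by 6.98, OAS2 by 6.4, ISG20 by 6.35, IFIT2 by 6.30, RTP4 by 6.07, FCN1 by 5.85 and SOCS1 by 5.76 (SE 0.41). CXCL10 rose by 6.16 (SE 0.80, adjusted p = 3.04e-09), like CXCL9 limited by the top of the scale, IRF1 by 4.18 (SE 0.42, adjusted p = 1.73e-12) and HLA-DRA by 0.92 (SE 0.15, adjusted p = 7.07e-07, 9 of 10 persons).

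CLDN10 and CA6 were among the largest falls in both disease states. Tissue marker lists were tested separately and are given further below. CLDN10, a tight junction gene, fell by 4.33 in healthy skin (SE 0.37, adjusted p = 2.45e-14, lower in 8 of 8 persons) and by 3.88 in psoriatic skin (SE 0.33, 10 of 10 persons). CA6, a secreted carbonic anhydrase gene, fell by 3.32 and 3.40, AQP5, a water channel gene of secretory glands, by 3.20 (SE 0.42) and 2.89, RERGL by 3.07 and 3.71, SLC47A1 by 2.91 and 3.05, SEMA5A by 2.84 and 3.69, ABCA8 by 2.76 and 3.27, and ENDOU by 2.66 and 2.93. Named in healthy skin only were SLC14A1 (-3.19), the mast cell protease gene CTSG (-3.05), CRISP3 (-3.03), the elastin gene ELN (-2.98), FMO5 (-2.81) and NCALD (-2.73). ROPN1B fell by 2.72 in healthy skin and was at least 4.59-fold lower in psoriatic skin, where it reached the floor. In psoriatic skin, LGR5, a hair follicle stem cell gene, fell by 4.39 (SE 0.47, adjusted p = 1.8e-11), SCUBE2 by 3.65 (SE 0.22), IL20RA by 3.31, the melanocyte gene MLANA by 3.27, TP53AIP1 by 3.21, BHLHE41 by 3.02 and ACACB by 2.97.

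Healthy and psoriatic skin shared most of these genes. Of the risen genes, 36 passed the threshold in healthy skin only and 115 in psoriatic skin only. For fallen genes these numbers were 53 and 252, with 377 in common, where 32.0 would be shared if the lists were independent. Passing in a single disease state is not a test of a difference between them. Psoriatic skin had more arrays and a smaller median SE (0.113 against 0.126), which makes passing easier there. For the difference between responses, tested directly, 0 genes passed. By limma, 0 genes passed in opposite directions. Across the 8446 genes, the log2 fold changes had a Pearson correlation of 0.951 and a Spearman correlation of 0.908, with a slope of 1.06 and the same sign in 87.5% of genes. This is a correlation across genes, which are not independent replicates, and both comparisons come from different persons with no shared arrays.

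**Figure D2:**
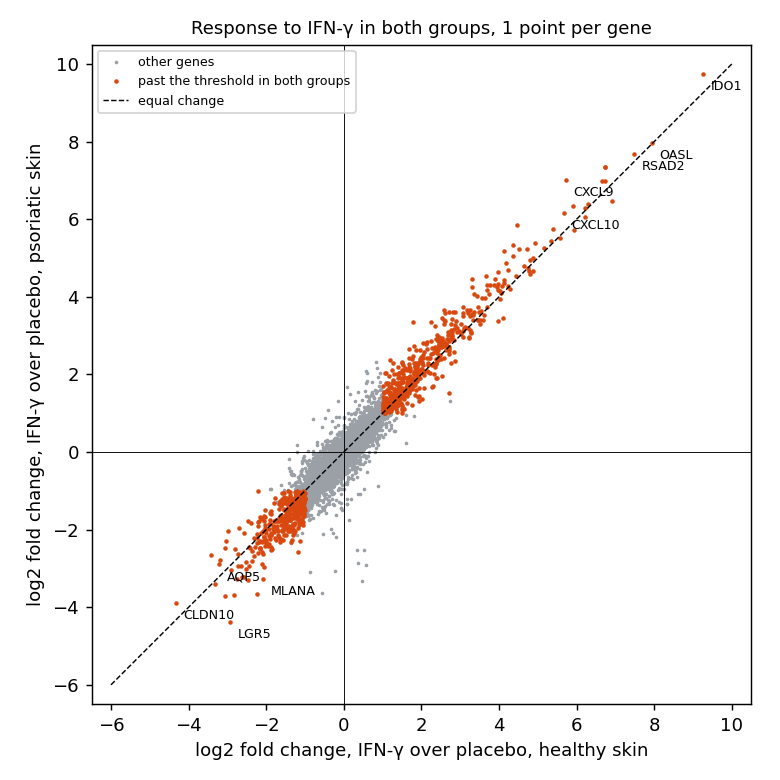
Log2 fold change after IFNγ against placebo in healthy skin (x axis) and in psoriatic non-lesional skin (y axis), one point per gene for 8446 genes. Points past the threshold in both comparisons lie along the diagonal, with 0 genes past it in opposite directions.

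Interferon-related lists rose as sets after IFNγ. All 30 tested type I interferon antiviral genes rose in both disease states, with a median of 4.23 in healthy skin (preset adjusted p = 1.33e-32, adjusted p = 0.249 with an estimated correlation) and 4.38 in psoriatic skin (preset 9.26e-30, 0.265 with an estimated correlation). Examples were RIGI, a sensor of viral RNA (5.34, SE 0.33, and 5.43), and SAMD9 (4.04 and 4.10). Of 16 MHC class I and immunoproteasome genes, which make and load the peptides shown to CD8 T cells, 15 rose in healthy skin (median 1.48, preset 3.27e-09, 0.249 estimated) and 16 in psoriatic skin (median 1.56, preset 1.33e-09, 0.265 estimated), among them TAP1 (2.76, SE 0.26, and 3.13), TAPBP (1.63 and 1.90) and PSME1 (1.33 and 1.37). Of 12 MHC class II genes, 11 rose in each (medians 0.89 and 1.03, preset 3.13e-06 and 1.13e-06, 0.249 and 0.286 estimated), led by the class II master regulator CIITA (2.70, SE 0.29, and 3.01) and CTSS (3.54 and 3.63). Of 12 JAK-STAT and IRF signalling genes, 10 rose in each (medians 1.54 and 1.93, preset 3.13e-06 and 3.98e-07, 0.249 and 0.265 estimated). Examples were IRF7 (3.31, SE 0.28, and 3.56) and IRF8 (2.57 and 2.87). Both tested GBP family GTPases rose, GBP1 by 2.78 (SE 0.30) and 3.01 and GBP2 by 2.46 and 2.75 (list preset 0.00456 and 0.00478, 0.281 and 0.265 estimated). All 4 tested apolipoprotein L genes rose, such as APOL6 (4.81 and 4.96, list preset 1.54e-05 and 2.38e-05, 0.249 and 0.265 estimated). So did the 3 tested genes of a longer tryptophan and kynurenine list, IDO1, WARS1 (4.13 and 4.35) and KYNU (2.44 and 2.62, list preset 0.000254 and 0.000372, 0.249 and 0.265 estimated). Counts adjusted over the list alone were the same for these 7 lists.

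Chemokine and immune regulation lists rose as well. Of 17 leukocyte chemokines, 12 rose in healthy skin (median 1.62, preset 1.65e-05, 0.249 with an estimated correlation) and 14 in psoriatic skin (median 2.03, preset 1.52e-07, 0.265 estimated). Examples were CX3CL1 (3.21 and 3.63) and CCL5 (2.80 and 3.03), while CXCL12 fell in both. Of 9 Th1, Th17 and IL-23 axis genes, 6 rose and 1 (IL18) fell in each (medians 1.10 and 1.21, preset 0.00676 and 0.00266, 0.249 and 0.265 estimated), with IL12RB2, a receptor subunit of Th1 cells, up by 4.73 (SE 0.39) and 5.23 and IL15 by 3.50 and 3.61. Of a longer inhibitory list, the 3 genes tested, LGALS9 (2.73 and 2.92), TNFAIP3 (1.42 and 1.65) and IL1RN (0.90 and 1.11), rose (preset 0.000697 and 0.000564, 0.249 and 0.265 estimated). Among 13 complement genes, 7 rose and 3 fell in healthy skin and 6 rose and 3 fell in psoriatic skin; CFB rose by 4.87 (SE 0.31) and 4.68 and C7 fell by 2.06 and 2.20, and the list was not past the preset test (0.0621 and 0.0891, 0.470 and 0.645 estimated). Endothelial adhesion genes split into 4 up and 4 down of 8, with ICAM1 up by 3.43 (SE 0.34) and 4.03 and CD34 down by 1.73 and 1.99; their median was -0.04 and -0.15 while the mean was 0.53 and 0.51 (preset 0.841 and 0.827, 0.889 and 0.821 estimated). Counts adjusted over the list alone were the same for these 5 lists.

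Markers of several leukocyte types were higher after IFNγ. Of 11 T cell markers, 8 rose in healthy skin and 10 in psoriatic skin (medians 1.03 and 1.01, preset 0.000163 and 2.48e-05, adjusted p = 0.249 and 0.265 with an estimated correlation), with the kinase gene LCK up by 3.10 (SE 0.38) and 3.19 and CD2 by 2.62 and 2.81. Of 11 NK and cytotoxic cell markers, 10 rose and 1 (NCAM1) fell in each (medians 1.85 and 2.41, preset 1.54e-05 and 2.95e-06, 0.249 and 0.265 estimated), among them the granule genes PRF1 (3.28, SE 0.29, and 3.10) and GNLY (3.45 and 3.41). Macrophage markers rose in 12 of 19 genes in healthy skin and 13 in psoriatic skin, with 1 and 2 falls (medians 1.05 and 1.62, preset 0.00273 and 2.38e-05, 0.516 and 0.318 estimated). Examples were CCR1 (3.66 and 4.53) and CD300A (3.29 and 4.25). Dendritic cell markers rose in 10 and 11 of 15, with 2 and 1 falls (medians 1.13 and 1.34, preset 0.000558 and 1.22e-05, 0.249 and 0.265 estimated), led by BATF3 (4.17, SE 0.28, and 4.86) and LAMP3 (4.14 and 4.43). Neutrophil markers rose in 7 and 9 of 10, with 1 fall (ELANE) in each (medians 1.80 and 2.13, preset 0.000683 and 2.38e-05, 0.382 and 0.265 estimated). Examples were BCL2A1 (4.51, SE 0.37, and 5.25) and FPR1 (4.37 and 5.35). Of 4 B and plasma cell markers, CD79B fell in healthy skin and CD27 rose in psoriatic skin (preset 0.899 and 0.928, 0.974 and 0.986 estimated); in psoriatic skin the median was -0.44 while the test direction was up. Of 3 red cell and platelet markers, 0 passed by limma in healthy skin and HBD rose by 0.99 in psoriatic skin (medians 0.08 and 0.19, preset 0.977 and 0.544, 0.889 and 0.627 estimated), and in healthy skin the preset test pointed down. Adjusted over the list alone, 2 macrophage markers fell in healthy skin and 0 B cell markers did; the other counts of these lists were the same. Changes within resident cells and entry of leukocytes were not separated here.

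Lists of mast cell, melanocyte, fibroblast, sweat gland, adipocyte and nerve markers were lower after IFNγ, the nerve list by the preset test in healthy skin only. Mast cell markers fell in 9 of 10 genes in healthy and 8 in psoriatic skin (medians -1.74 and -1.12, preset 2.52e-05 and 0.00608, adjusted p = 0.249 and 0.291 with an estimated correlation), with the monoamine transporter gene SLC18A2 down by 2.15 (SE 0.25) and 1.69 and HPGDS by 2.03 and 1.49. All 8 melanocyte markers fell in healthy and 7 in psoriatic skin (medians -1.15 and -1.37, preset 0.000663 and 0.00111, 0.249 and 0.265 estimated), including the pigment enzyme gene TYR (-2.28 and -2.44) and OCA2 (-1.96 and -2.42). Fibroblast and matrix genes fell in 15 of 19 in each (medians -0.65 and -0.72, preset 0.000669 and 0.00737, 0.323 and 0.391 estimated). Examples were POSTN (-1.86, SE 0.22, and -1.85). Sweat gland markers fell in 8 of 10 in each (medians -2.0 and -1.71, preset 0.000163 and 0.00737, 0.249 and 0.265 estimated). Examples were SCGB2A2 (-2.38 and -1.84). Adipocyte markers fell in 7 and 10 of 11 (medians -1.09 and -2.09, preset 0.0291 and 0.00814, 0.382 and 0.265 estimated). Examples were FABP4 (-1.99 and -2.33). Nerve and Schwann cell markers fell in 6 and 5 of 7 (medians -0.83 and -0.94, preset 0.0117 and 0.0703, 0.249 and 0.265 estimated). Examples were CDH19 (-2.20, SE 0.26, and -1.81). Adjusted over the list alone, 10 and 9 mast cell markers, 8 melanocyte markers in each, 16 fibroblast genes in healthy skin (with 1 rise) and 8 adipocyte markers in healthy skin fell; the other counts were the same.

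The remaining structural lists did not pass the preset test in either disease state. Endothelial and pericyte markers split, with 2 rises (KDR and FLT1, each 0.93) and 6 falls in healthy skin and 3 rises and 7 falls in psoriatic skin, CLDN5 falling by 1.77 in both (medians 0.01 and -0.27, preset 0.463 and 0.259, 0.598 and 0.722 with an estimated correlation); in healthy skin the mean was -0.28 and the test pointed down. Of 6 sebaceous gland markers, 2 fell in each, FA2H by 1.89 and 2.24 and HAO2 at least 3.55-fold and 2.13-fold (preset 0.380 and 0.413, 0.567 and 0.530 estimated). Of 8 hair follicle keratins, 0 passed by limma in healthy skin, and in psoriatic skin KRT31 (-2.34), KRT35 (-3.08), KRT85 (-3.06) and TCHH (-3.64) fell (medians -0.39 and -2.43, preset 0.891 and 0.310, 0.878 and 0.738 estimated), or 2 when adjusted over the list alone. Of 7 muscle markers, 2 and 3 fell, with MYH11 lower by 0.87 and 1.15 (preset 0.460 and 0.427, 0.605 and 0.738 estimated). Basal keratinocyte genes had 3 rises and 1 fall in healthy skin and 2 rises and 2 falls in psoriatic skin among 8, with ITGA3 up by 0.76 and 0.82 and DST down by 0.71 and 0.81 (preset 0.660 and 0.585, 0.728 and 0.722 estimated). The other counts adjusted over the list alone were the same.

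Keratinocyte, growth and stress lists were mixed. Of 17 keratinocyte differentiation genes, 7 fell in healthy skin and 10 in psoriatic skin (medians -0.32 and -0.58, preset 0.0487 and 0.0616, adjusted p = 0.304 and 0.448 with an estimated correlation), among them the barrier gene FLG (-0.88 and -0.85) and DSC1 (-0.97 and -0.81). Of 22 genes reported in psoriatic-lesion keratinocytes, 9 and 10 rose and 1 (RHCG) fell in each (medians 0.64 and 0.70, preset 0.0585 and 0.0512, 0.529 and 0.448 estimated), with IL36G up by 1.23 and 1.17. Of 19 cell cycle genes, CCNB1 and CCNB2 rose and 5 genes fell in healthy skin, and 15 fell in psoriatic skin (medians -0.04 and -0.82, preset 0.746 and 0.00470, 0.974 and 0.314 estimated), including TYMS (-0.67 and -1.59) and MCM2 (-0.71 and -1.09). Immediate early genes had 6 rises and 3 falls in healthy skin and 9 and 2 in psoriatic skin among 15 (medians 0.60 and 0.64, preset 0.138 and 0.0132, 0.516 and 0.391 estimated), with the stress transcription factor gene ATF3 up by 3.27 (SE 0.28) and 3.07 and IER3 down by 1.66 and 1.27. Wound repair genes had 5 and 6 rises and 1 fall (MMP9) in each among 12 (medians 0.28 and 0.69, preset 0.235 and 0.0289, 0.581 and 0.378 estimated), with PTGS2 up by 4.01 (SE 0.29) and 3.94. Of 17 cholesterol and lipid synthesis genes, 3 and 6 fell and 0 rose by limma (medians -0.24 and -0.34, preset 0.356 and 0.366, 0.594 and 0.448 estimated), with SCD down by 0.94 and 1.31. Adjusted over the list alone, 3 cell cycle genes fell and 0 rose in healthy skin, 8 immediate early genes rose in healthy skin and 4 cholesterol genes fell in psoriatic skin; the other counts were the same.

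By list, 15 were raised and 7 lowered in healthy skin and 17 raised and 6 lowered in psoriatic skin with the preset correlation, and 0 with an estimated correlation. In the per-person exact permutation test, 18 lists were raised and 8 lowered in healthy skin (8 persons, smallest adjusted p 0.0122) and 20 raised and 11 lowered in psoriatic skin (10 persons, smallest adjusted p 0.00306). The type I interferon list was among those at these smallest values in both.

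**Figure D3:**
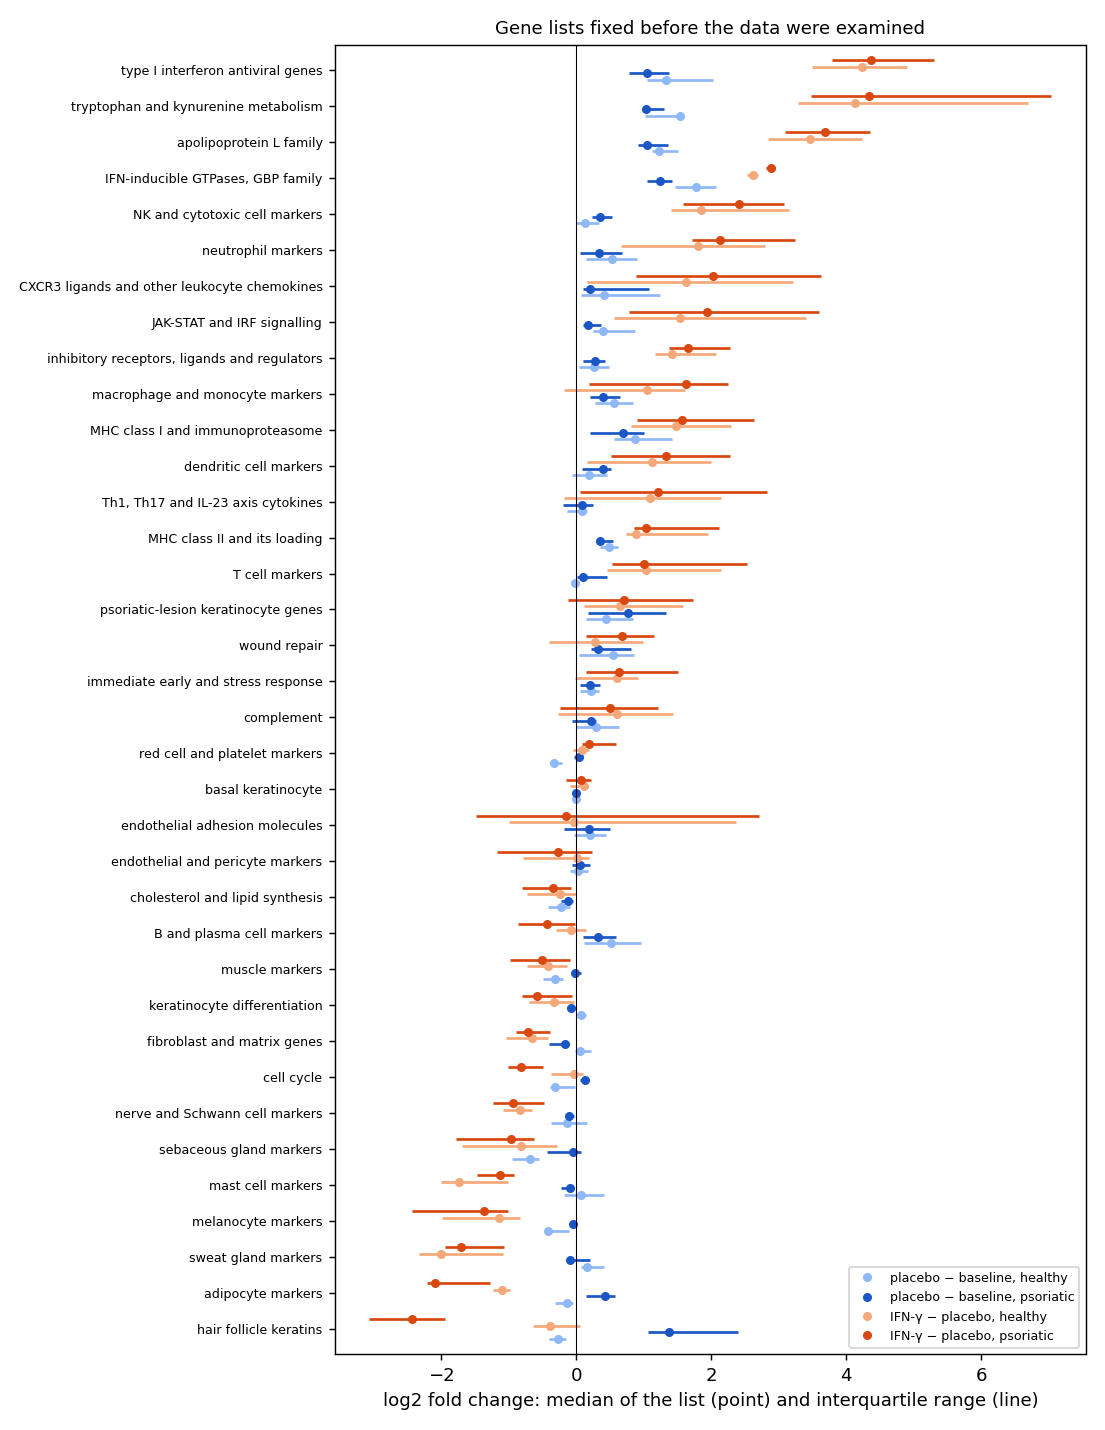
Median log2 fold change (point) and interquartile range (line) of each of the 36 gene lists after IFNγ against placebo and after placebo against baseline, in healthy and in psoriatic non-lesional skin. The type I interferon antiviral list has medians of 4.23 and 4.38 after IFNγ and 1.33 and 1.04 after placebo.

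No gene passed the threshold for a difference between the IFNγ responses of psoriatic and healthy skin in the main setting. By limma, 0 of 8446 genes passed for the difference between responses (smallest adjusted p 0.198), with 581 genes (6.88%) at an unadjusted p under 0.05. The known targets IRF1 (0.49, SE 0.63, adjusted p = 0.873) and HLA-DRA (0.02, SE 0.23, 0.988) did not pass. Without the 2 outlying placebo arrays, healthy replicate 5 and psoriasis replicate 5, these differences were 0.30 (SE 0.43) and 0.07 (SE 0.20). The 2 arrays thus widened the error for these genes. For IDO1 (0.48, SE 1.04, 0.941) most placebo arrays lay near the lowest value of its probe set, so both responses may be understated and their difference does not compare them. For CXCL10 (0.47, SE 1.2, 0.949) and CXCL9 (1.29, SE 1.15, 0.818) the difference reflects the placebo arrays alone, since both were near the top of the scale after IFNγ, and it does not compare the responses. The smallest p-values were those of LILRB1, an inhibitory receptor gene of leukocytes (1.49, SE 0.32, adjusted p = 0.198, responses of 2.32 and 0.83), AOAH (0.88, SE 0.20, 0.198), SCUBE2 (-1.40, SE 0.33, 0.248), CNNM4 (-0.62, 0.248) and KIF11 (-1.42, SE 0.36, 0.278), none of which passed. The 95% confidence interval of the difference had a median half-width of 0.34 log2 (1.27-fold) and lay within 2-fold in 87% of the 8446 genes tested. Differences above 2-fold are thus excluded for most genes tested but not for the remainder. Of these genes, 1359 had passed after IFNγ in either disease state, and the share among them was not computed. For IRF1 the interval reached beyond 2-fold. Leaving out 1 person gave CCL7 (without psoriasis replicate 3), CCL4 (without psoriasis replicate 5), LILRB1 (without healthy replicate 9) or LILRB1 and SCUBE2 (without psoriasis replicate 10), genes chosen after their values were seen. LILRB1 also passed with all probe sets and with the mean of a gene's probe sets, and CCL4 and LILRB1 with array weights.

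As lists, 13 were raised and 2 lowered in the difference between responses with the preset correlation, and 0 with an estimated correlation (smallest adjusted p 0.463). Cell cycle genes, which replicate and divide cells, had a median difference of -0.76 (preset 6.21e-11), with 9 members lower when adjusted over the list alone and 0 over all genes. Hair keratins moved the same way (median difference -1.90, preset 0.044, 0 members adjusted over the list alone), but with baseline as the control of IFNγ the median was -0.25 (adjusted p = 0.981) and the test direction changed. Both lists were higher in psoriatic than in healthy skin after placebo with the preset correlation, but did not pass with an estimated one or when persons were permuted. Macrophage and monocyte markers had a median difference of 0.50 (preset 1.52e-06), with 1 member adjusted over the list alone. In the test that permuted persons between disease groups, 0 lists passed, and the smallest adjusted p, 0.125, was that of the cell cycle list. Adjusted over the list alone, 16 members of all lists passed in this comparison.

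At baseline, no gene passed the threshold between psoriatic non-lesional and healthy skin, which does not show that they were equal. By limma 0 of 8446 genes passed (smallest adjusted p 1), with 350 at an unadjusted p under 0.05, and the 95% interval lay within 2-fold in 92% of genes (median half-width 0.30, 1.24-fold). The smallest p-values were those of GGH (9.70 ± 0.25 in psoriatic and 8.84 ± 0.74 in healthy skin, difference 0.86, SE 0.21), OSTF1 (0.65), the epidermal keratin gene KRT2 (15.40 ± 0.06 and 15.03 ± 0.41, difference 0.37, near the top of the scale, where differences cannot be read), CACNA2D2 (-0.44) and WDR5B (-0.50), each with adjusted p = 1. The keratinocyte differentiation list was higher in psoriatic skin (median 0.46, preset 3.8e-12, adjusted p = 0.483 with an estimated correlation), with 4 members adjusted over the list alone and 0 over all genes. It was the single list past the permutation of persons (adjusted p = 0.0428). Without the arrays with signs of poor RNA, its median was 0.47 (preset 2.37e-11) and the exact permutation adjusted p was 0.173 (9 psoriatic and 7 healthy arrays). Also past the preset test were psoriatic-lesion keratinocyte genes (0.32, 0.00089), immediate early genes (0.26, 0.0155) and fibroblast genes (0.22, 0.000813), all higher, and muscle (-0.77, 0.00528) and nerve markers (-0.41, 0.000776), both lower, with estimated-correlation values from 0.319 to 0.569. Without the poor-RNA arrays the immediate early list did not pass (0.15, 0.276) and the psoriatic-lesion keratinocyte median was 0.60 (0.000249). Healthy baseline arrays had the widest GAPDH 3' minus 5' difference, 1.17 ± 1.52 (n = 10), against 0.59 ± 0.48 (n = 10) in psoriatic baseline arrays. Healthy replicate 6 carried much of this, as the healthy mean was 0.74 ± 0.71 (n = 9) without it.

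Placebo injection was followed by higher interferon-response genes than at baseline. In healthy skin 57 genes rose and 0 fell 2-fold by limma (89 higher and 22 lower at any fold, 1261 at an unadjusted p under 0.05), and in psoriatic skin 28 rose and 0 fell (45 and 2, with 979). All 28 were among the 57, where 0.189 would be shared if independent: APOL1, APOL3, BST2, CCL19, CFB, CX3CL1, CXCL11, GBP1, HERC6, IFI27, IFI35, IFI44L, IFIT1, IFIT3, IRF1, IRF9, MX1, OAS2, OAS3, PLAAT4, PSMB10, PSMB9, SCO2, SP110, TAP2, TLR3, UBE2L6 and WARS1. The median rise was 1.51 in each, while the same genes rose by a median of 4.85 and 5.09 from baseline to IFNγ, read against the same baseline arrays. Against placebo, 562 and 641 of all 8446 genes were at least 2-fold higher after IFNγ in healthy and psoriatic skin. Of the 57 genes, 56 were, as were 28 of the 28, though these comparisons share the placebo arrays with opposite sign. The exception was PLA2G2A, a secreted phospholipase gene, which rose by 2.06 after placebo (adjusted p = 0.00755) and did not pass between IFNγ and placebo (0.52, adjusted p = 0.367). At any fold, the 2 falls in psoriatic skin were RYR1 (-0.79, SE 0.18, adjusted p = 0.0168, -0.87 in healthy skin) and CDC14A (-0.47, adjusted p = 0.0208), chosen after their values were seen.

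The largest placebo rises were in antiviral and chemokine genes. CXCL11 rose by 4.07 in healthy skin (SE 0.70, adjusted p = 0.000168, 8 of 8 persons) and by 3.06 in psoriatic skin (SE 0.64, adjusted p = 0.00723, 8 of 10 persons), IFI44L by 3.43 (SE 0.39, adjusted p = 2.94e-08) and 2.27 (SE 0.36, adjusted p = 7.44e-05), and IRF1 by 3.42 (SE 0.45, adjusted p = 9.46e-07) and 2.69 (SE 0.42, adjusted p = 7.44e-05). OAS2 rose by 2.82 and 2.36, IFI35 by 2.59 and 2.0, the immunoproteasome gene PSMB10 by 2.42 (SE 0.31) and 1.92 (SE 0.29), GBP1 by 2.38 and 1.61, APOL1 by 2.37 (SE 0.33) and 2.01 (SE 0.30), PLAAT4 by 2.14 and 1.79 and IRF9, part of the type I interferon transcription complex, by 1.52 (SE 0.13, adjusted p = 9.97e-13) and 1.05 (SE 0.12, adjusted p = 3.34e-08). In healthy skin TYMP (2.73), IFI44 (2.49), HERC6 (2.43), XAF1 (2.38) and OAS1 (2.10) rose too. CXCL10 rose by 3.80 in healthy skin (SE 0.87, adjusted p = 0.0086, 7 of 8 persons) and CXCL9 by 4.34 (SE 0.83, adjusted p = 0.000784); in psoriatic skin neither passed (1.91, adjusted p = 0.34, 5 of 10 persons, and 2.31, adjusted p = 0.165). IDO1 did not pass in either (1.54, adjusted p = 0.320, and 1.03, adjusted p = 0.588), nor did HLA-DRA (0.53, 0.1, and 0.40, 0.259). Without the placebo arrays of healthy replicate 5 and psoriasis replicate 5, the IDO1 values were 0.43 (SE 0.12, adjusted p = 0.0611) and 0.02 (SE 0.11, adjusted p = 0.97), and in psoriatic skin those of CXCL10, CXCL9 and HLA-DRA were 1.21, 1.47 and 0.26. The difference between the placebo responses of psoriatic and healthy skin was not tested.

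As lists, 16 were raised and 0 lowered after placebo in healthy skin and 19 raised and 1 lowered in psoriatic skin with the preset correlation, and 0 with an estimated correlation. Type I interferon genes rose in 21 of 30 in healthy skin (27 adjusted over the list alone, median 1.33, preset 2.15e-51, 0.245 estimated) and in 11 in psoriatic skin (29 adjusted over the list alone, median 1.04, preset 9.11e-39, 0.319 estimated). MHC class I genes rose in 12 of 16 (14 adjusted over the list alone, median 0.87, preset 2.38e-34, 0.300 estimated) and in 6 (11 adjusted over the list alone, median 0.69, preset 5.05e-21, 0.319 estimated). The JAK-STAT, chemokine, MHC class II, GBP, apolipoprotein L, tryptophan, complement, psoriatic-lesion keratinocyte, wound repair, immediate early, macrophage, dendritic cell and neutrophil lists were raised in both disease states at the preset value, with estimated values from 0.101 to 0.475. MMP9, a matrix-degrading enzyme gene, rose in both by under 2-fold (0.91, adjusted p = 0.0401, and 0.88, adjusted p = 0.0415). In healthy skin the keratinocyte differentiation list was raised too (0.07, preset 0.0346), and with an estimated correlation its direction was down (0.955). In psoriatic skin, cell cycle (0.13, 0.0247), NK (0.35, 0.000416), adipocyte (0.43, 0.0175) and hair keratin genes (1.38, 0.00305) were raised and fibroblast genes lowered (-0.17, 0.000643). These lists did not pass in healthy skin, and the difference was not tested. Without the poor-RNA arrays the adipocyte list did not pass (0.27, 0.139), nor did the immediate early list in healthy skin (0.12, 0.0613). In the per-person exact permutation test, 9 lists were raised and 0 lowered in each, at smallest adjusted p of 0.0313 in healthy skin and 0.0176 in psoriatic skin, the type I interferon and MHC class I lists among them. Over all lists, 90 members passed in each comparison when adjusted over the list alone.

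The size of the placebo signature rested partly on 2 persons. Without healthy replicate 5 the count in healthy skin was 32, and without psoriasis replicate 5 the count in psoriatic skin was 11. Leaving out only their placebo arrays gave 40 and 17 genes, and CXCL11 then rose by 3.36 (adjusted p = 8.75e-06) in healthy and by 2.33 (adjusted p = 0.00264) in psoriatic skin. The same omission raised the counts after IFNγ against placebo to 1108 and 1377, with IDO1 rising by 10.37 and 10.75. With no person block the psoriatic placebo count was 13, as it was with person as a fixed block. With only the groups of the comparison in the fit the counts were lower in both disease states. Without the poor-RNA arrays the psoriatic count was higher, as given in the section on processing.

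After injection, psoriatic and healthy skin again had no gene past the threshold in the main setting. After placebo 0 genes passed by limma (482 at an unadjusted p under 0.05); SNN (0.54, SE 0.11) and ETF1 (0.41, SE 0.08) came closest at adjusted p = 0.0546, then METTL9 (0.34, 0.463), TNFAIP1 (0.39, 0.616) and GGH (0.85, 0.616). After IFNγ 0 passed (754 at an unadjusted p under 0.05); the smallest p-values were those of AEN (0.84, SE 0.18, adjusted p = 0.157), FANCE (-0.97, SE 0.21, 0.157), the chemokine genes CCL4 (1.24, SE 0.28, 0.177) and CCL7 (1.12, 0.179), and LILRB1 (1.27, 0.179). The 95% interval lay within 2-fold in 90.1% and 89.7% of genes. With no person block 4 genes passed after IFNγ, CCL4, CCL7, LILRB1 and SLAMF7, chosen after their values were seen. With array weights 13 passed, and 1 passed without the filter (ADGRE2), with all probe sets (LILRB1) and with the mean of a gene's probe sets (LILRB1). Leaving out 1 person gave CCL4 (without psoriasis replicate 1, and without replicate 5), CCL7 (without psoriasis replicate 3) or LILRB1 (without healthy replicate 9).

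By list, with the preset correlation, 4 were raised and 4 lowered in psoriatic against healthy skin after placebo, and 10 raised and 1 lowered after IFNγ, with 0 in each at an estimated correlation (smallest adjusted p 0.473 and 0.436). After placebo, psoriatic-lesion keratinocyte genes (0.52, preset 0.000332), keratinocyte differentiation (0.24, 0.00372), cell cycle (0.27, 0.0135) and hair keratins (2.70, 0.00141) were higher, and chemokines (-0.36, 0.0311), MHC class I (-0.15, 0.0134), type I interferon genes (-0.20, 0.00785) and nerve markers (-0.37, 0.00372) lower. After IFNγ, the largest raised medians were those of neutrophil (0.66, 0.000454), mast cell (0.64, 0.00322) and psoriatic-lesion keratinocyte genes (0.57, 2.07e-05), followed by NK (0.32, 0.00352), macrophage (0.31, 0.000693), dendritic cell (0.30, 0.00103), immediate early (0.29, 2.07e-05), inhibitory (0.28, 0.0442), keratinocyte differentiation (0.21, 0.00247) and chemokine genes (0.04, 0.048), while cell cycle genes were lower (-0.39, 8.88e-05). Adjusted over the list alone, 4 members passed after placebo and 11 after IFNγ. In the permutation of persons 0 lists passed after placebo (smallest adjusted p 0.584) or after IFNγ (0.232).

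**Figure D4:**
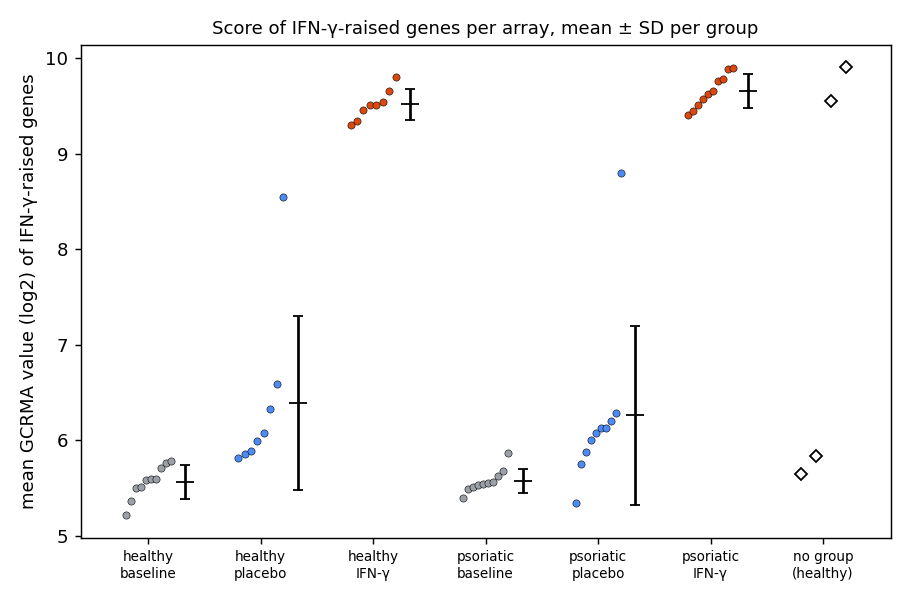
Mean log2 signal of the genes raised at least 4-fold by IFNγ in both disease states when the arrays of both persons with replicate number 5 are left out, one point per array, sorted by level within its group, with the mean and SD beside it and the 4 arrays in no group shown apart. Placebo arrays of healthy replicate 5 (8.54) and psoriasis replicate 5 (8.80) lie between the other placebo arrays and the IFNγ arrays.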

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

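Apart from the injury lists, the other splits of the arrays and the first form of the mixing test, each test of an explanation here was chosen only after the result was seen, as were the fits without single arrays or with an RNA quality term.

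Single arrays far from the rest of their group were found in 12 of 42 group values tested, where chance flags about 1 in 20 groups. The placebo arrays of healthy replicate 5 and psoriasis replicate 5, from different persons, account for 5 of them. IDO1 was 11.77 in the healthy placebo array (next array 4.05) and 12.69 in the psoriatic one (next 3.06), CXCL9 was 14.29 in the healthy array and 14.86 in the psoriatic one (next 9.33), and IRF1 was 12.59 in the psoriatic array (next 9.85). At baseline, IDO1 was 2.83 in healthy replicate 3 (next 2.63) and 3.44 in psoriasis replicate 4 (next 3.0), both close to the floor. The GAPDH 3' minus 5' difference was 5.07 at baseline in healthy replicate 6 (next 2.23), and in psoriasis replicate 4 it was 1.92 at baseline (next 0.56) and 2.29 after placebo (next 1.25). The ACTB difference was 1.6 in the IFNγ array of healthy replicate 5 (next 0.76) and 2.0 at baseline in psoriasis replicate 4 (next 0.81).

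The 2 outlying placebo arrays scored 8.54 and 8.80 as the mean log2 signal of IFNγ-raised genes. Other placebo arrays scored 5.82 to 6.59 in healthy skin and 5.34 to 6.29 in psoriatic skin, and IFNγ arrays 9.30 to 9.90. An exchange of the person's placebo and IFNγ arrays is argued against, because their IFNγ arrays score at least 2.88 above the highest other placebo array. Poor RNA is argued against as well, since 4 of 4 control probe differences of these arrays lay inside the range of the other placebo arrays.

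Material of the same person's IFNγ biopsy in the placebo sample stays open. From 191 rising genes the share would be 50.6% in the psoriatic array, which predicts a median change of -0.70 in 366 falling genes. The observed median was -0.91, at -0.76 SD of the other placebo arrays from the prediction. In the healthy array the share would be 48.4% (quartiles 30.8% to 78.9%), the prediction is -0.48 and the observed median -0.92, a distance of -2.68 SD. That distance met the bound first written for excluding the explanation, 2 SD in either array, before the result was seen. The test in its present form was written afterwards, because the first bound ignored the spread of the share: at its upper quartile the prediction is -0.89, so the healthy array cannot be told apart. A strong local IFNγ effect in the placebo skin of these persons is a candidate explanation that was not tested.

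Interferon-response genes were higher after placebo than at baseline in both disease states. The 2 outlying arrays do not account for all of it, since without them the smaller of the counts was 17 genes (psoriatic skin; 40 in healthy skin). RNA quality as the whole cause is argued against by 29 genes (51 in healthy skin) with the ACTB difference as a covariate. A small share of IFNγ-injected material in every placebo sample is argued against at the shares estimated here. They came from 17 genes that passed after placebo in both disease states, a choice that can overstate the share. A share of 3.87% or 2.77% predicts median rises of 3.85 and 3.66 in FCGR1BP, IDO1, IFIT2, OASL, RSAD2 and RTP4. These genes lie at the floor at baseline and were chosen because that share predicts a level clear of it. The observed rises were 0.50 and 0.44, a gap of at least 3.23. At the lower quartile of the share (2.47% and 1.72%) the gaps were 2.77 and 2.60. Smaller shares were not tested. The genes of this test were redefined after a first version with the same verdict.

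Injury by needle and biopsy may contribute to the placebo signature. The wound repair and immediate early lists were raised in 4 of 4 comparisons with the preset correlation, which met the bound set before the result was seen. Members of both lists also responded to IFNγ against placebo, with rises such as PTGS2 and ATF3 and falls of MMP9 and IER3. A raised list therefore cannot separate injury from exposure to IFNγ. The evidence is weak: with an estimated correlation the adjusted p was 0.101 and 0.319 for wound repair and 0.382 and 0.319 for immediate early genes, and in the per-person exact permutation it was 0.0563 and 0.127, and 0.480 and 0.114. Without the poor-RNA arrays, the immediate early list did not pass in healthy skin (median 0.12, preset 0.0613). Spread of IFNγ from another injection site of the same person is a further explanation that was not tested.

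For 4 arrays of 2 healthy persons, title and characteristic name opposite injections. On the score of IFNγ-raised genes, the arrays whose characteristic gives IFNγ had 9.91 (healthy replicate 6) and 9.56 (healthy replicate 8), above every placebo array, and those whose characteristic gives placebo had 5.65 and 5.84. Both replicate 6 values lay outside the range of the group their characteristic names (placebo 5.82 to 6.59 without replicate 5, IFNγ 9.30 to 9.81), and 5.65 lay within the healthy baseline range of 5.22 to 5.79. The titles as the source of the injection are argued against, with 0 of 4 arrays on the side of their title, and 4 of 4 were on the side of their characteristic. These values are consistent with exchanged titles, but the arrays stayed in no group because the values are the outcome. No biological explanation was tested.

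In the difference between the IFNγ responses, psoriatic minus healthy, 15 lists passed with the preset correlation. Their median differences were 0.21 (JAK-STAT and IRF signalling), 0.42 (chemokines), 0.12 (MHC class I), 0.15 (type I interferon genes), 0.19 (immediate early), 0.38 (wound repair), 0.14 (T cell), 0.14 (NK), 0.50 (macrophage), 0.30 (dendritic cell), 0.63 (neutrophil), 0.50 (mast cell), 0.36 (sweat gland), -0.76 (cell cycle) and -1.90 (hair keratins). With an estimated correlation 0 of them passed, nor did any when persons were permuted between the disease groups. With baseline as the control of IFNγ, the medians for MHC class I (-0.13) and type I interferon genes (-0.18) changed sign and did not pass, and that for hair keratins shrank to -0.25 (adjusted p = 0.981) with a changed test direction.

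Probe sets without a single gene symbol also changed after IFNγ against placebo, 180 of 1548 in healthy skin (83 higher, 97 lower) and 197 in psoriatic skin (99 higher, 98 lower). After placebo 8 and 6 of them rose.

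Other splits of the same arrays into groups of the same sizes, 100 including the real one, were fitted for each comparison. Of the 100 splits, the real one had the highest count for IFNγ against placebo. In healthy skin this was 992 genes (highest other split 872, 1 split as large) and in psoriatic skin 1270 (892, 1). The real split was also highest for placebo against baseline, with 57 in healthy skin (43, 1) and 28 in psoriatic skin (21, 1). These ranks argue against chance, but 100 splits are too few to exclude it. For the comparisons with 0 genes past the threshold by limma, genes at an unadjusted p under 0.05 were counted. There, other splits exceeded the real count, so chance stays open. The difference between responses had 581 genes against 1045 in the highest other split (18 splits as large), and psoriatic against healthy skin had 350 against 1369 at baseline (56 splits), 482 against 2280 after placebo (37 splits) and 754 against 1056 after IFNγ (5 splits). At baseline and after placebo, the highest splits held several times the real count, which may reflect a structure of the samples. The highest of many splits does not by itself show such a structure, and the cause was not tested.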

How the results depend on the processing

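Chosen only after the data were seen were the settings without the placebo arrays of healthy replicate 5 and psoriasis replicate 5, with the ACTB difference as a covariate, and without the arrays with a GAPDH or ACTB difference of 1.5 or more. Where no cause is given, the cause was not tested. Of 9437 alternative values of 387 named gene results, 9088 kept direction and side of the threshold, 301 lost the threshold, 48 newly passed it and 0 reversed. Of the alternative list results, 622 kept both and 162 lost the threshold. The paired structure entered as a replicate block: without it the count after IFNγ was 945 in healthy and 1235 in psoriatic skin, and with person as a fixed replicate block 1000 and 1272. Placebo against baseline in psoriatic skin (28) fell to 13 without the replicate block and 13 with a fixed one, 8 with only its groups in the fit, 16 at adjusted p under 0.01 and 17 without the 2 placebo arrays, and rose to 44 without the poor-RNA arrays. In healthy skin (57) it was 36 with only its groups in the fit. With no fold threshold, which admits small changes, counts were 4341 and 5195 after IFNγ and 111 and 47 after placebo. The difference between responses gave 1 gene (LILRB1) with all probe sets, 1 (LILRB1) with the mean of a gene's probe sets and 2 (CCL4, LILRB1) with array weights. Psoriatic against healthy skin after IFNγ gave 4 without the replicate block (CCL4, CCL7, LILRB1, SLAMF7), 1 (ADGRE2) without the filter, 1 (LILRB1) with all probe sets, 1 (LILRB1) with the mean, and 13 with array weights.

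Leaving out each person gave 929 to 1130 and 1233 to 1343 genes after IFNγ, 32 (without healthy replicate 5) to 66 and 11 (without psoriasis replicate 5) to 39 after placebo, 0 to 2 for the difference between responses (CCL7 without psoriasis replicate 3, CCL4 without 5, LILRB1 and SCUBE2 without 10, LILRB1 without healthy replicate 9), 0 to 1 after IFNγ between disease states (CCL4 without psoriasis replicate 1 or 5, CCL7 without 3, LILRB1 without healthy replicate 9), and 0 to 0 at baseline and after placebo between them. The number of lists past the threshold was 0 in each of the 8 comparisons with an estimated correlation. Without the poor-RNA arrays it was 10 at baseline and 5 after placebo between disease states, against 6 and 8. With baseline as the control of IFNγ, the median difference between responses reversed for MHC class I (-0.13, adjusted p = 0.151) and type I interferon genes (-0.18, 0.309). For hair keratins it stayed negative (-0.25, 0.981) while the test direction changed, and the keratinocyte differentiation list after placebo in healthy skin changed test direction with an estimated correlation (median 0.069, adjusted p = 0.955). Adjusted over the list alone, 16, 4, 90, 90, 4 and 11 members passed for the difference between responses, at baseline, after placebo in healthy and psoriatic skin, and between disease states after placebo and after IFNγ. The correlation across genes between responses was 0.949 without the filter (11939 genes), 0.955 with the stricter one (7647) and 0.974 over genes past the threshold in either (1359). Values at the floor limit what can be read of falls in weakly expressed genes.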
